A study of Mus musculus with 7 samples.

How the data were processed

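Macrophages sorted by GFP and F4/80 from normal mouse brain (3 arrays) and from GL261 tumours (4 arrays) were profiled on Affymetrix mouse arrays with biotin-labelled cRNA. The labels do not say whether the normal brain mice carried GFP, so it is not known whether both groups were sorted alike. The deposited values are linear MAS5 signal intensities, 1 per probe set, which the authors made with MAS5 according to the labels. The MAS5 version and its detection calls are not given in the sources used here. On every array the mean signal without the lowest and highest 2% was about 500, so the arrays had been scaled to a common target, and no further scaling was applied. The replicates were not pooled, and 0 columns belonged to no sample.

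Of the 45101 probe sets 64 were control probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in the probe table. Gene symbols were checked against the RefSeq annotation of GRCm38.p6 through gene IDs, of which 204 did not match, and 0 symbols were changed. The annotation was used only for names, and no positions are given because the labels name no genome build. Each of the 18193 genes was represented by its probe set with the highest mean log2 value. Values were analysed as log2(signal + 6), where 6 is the 20th percentile of all values, which shrinks fold changes of genes with low signal. Genes were tested when the mean log2 value of their probe set was above 4.93, which left 12125. This was the 40th percentile of the means of all non-control probe sets. The analyses were run in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

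GL261 was compared with normal brain by limma with moderated variances that follow the mean signal, with two-sided tests and Benjamini-Hochberg adjustment over the 12125 genes. Genes at an adjusted p under 0.05 were called, and all adjusted p-values for genes are from limma. In all, 44 gene lists for cell types, activation programmes, metabolism and checks were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, and adjusted over the lists. The same lists were run with an estimated correlation and with fry. Single measures of the arrays were compared by two-sided exact permutation tests over the 35 splits of the arrays. The lists, the comparison, the rule for named genes and most alternative settings were fixed before the data were examined.

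The genes named were the 12 with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap and whose symbols were not clone or predicted names. From each list up to 3 called members in the direction of most called members and 1 in the other were named, or, where none was called, the members with the smallest p. A fixed set of macrophage and sex-linked genes was always named. Full statistics were limited to about 30 genes. Background was taken, after the values were seen, from 27 unspiked Bacillus control probe sets as the 95th percentile on each array, which was 4.19 to 4.70 on the log2 scale. Where all arrays of a group were at or under this level, a lower bound of the fold against the background is given in place of a fitted fold. This bound uses the mean of the other group and leaves out the spread between arrays, so it is no confidence limit.

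The alternative settings fixed beforehand were a pseudocount of 1 or 58, no filter or a filter at the 60th percentile, quantile normalization, median centring, the replicate number as a block, variances that do not follow the signal, array quality weights, all probe sets or their mean per gene, and leaving out each array. After the data were seen, a covariate of hybridisation control level (18 control probe sets), the removal of normal brain replicate 1 together with GL261 replicate 2, and the background bounds were added. The procedure was tested on simulated data in 10 runs of 12125 genes with 200 changed. It recovered 25.4% of genes changed by log2 1 and 59.2% of those changed by log2 2, and 4.62% of calls were false. A list of 20 genes shifted together was called, and 0 of 20 lists without a shift were. The simulated values followed the variance model of the fit, so the runs do not show that the share of false calls holds for the real arrays. The simulated genes also varied independently, so the runs do not show how often lists of correlated genes are called falsely. In the real lists the estimated correlation was, for example, 0.34 for endothelial and 0.85 for ribosomal genes. Probe sets with several symbols or none were used only where all probe sets were tested.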

Results

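The data were gene expression values of macrophages sorted from mouse brain by GFP and F4/80, measured on Affymetrix mouse whole-genome arrays in 3 preparations from normal brain and 4 from GL261 tumours. GL261 is a mouse glioma cell line that grows as a tumour after injection into the brain of C57/Bl6 mice. The tumour-bearing mice carried GFP-labelled bone marrow, and their tumours had grown for 21 days. The normal brain samples came from mice 8 weeks old, and the labels do not say whether these mice carried the labelled marrow as well. Brains were digested with papain before sorting. Each array gave a MAS5 signal, a linear intensity, for 45101 probe sets, of which 34945 had 1 gene symbol and stood for 18193 genes. After a filter on low values 12125 genes were tested. Precision is limited by the number of arrays, and the labels do not state whether arrays came from separate mice. The p-values for genes and for array measures therefore measure only the spread between these arrays. Those of camera compare the genes of a list with all other genes. Permutations over genes in a later part shuffle genes, not arrays.

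The median signal per array was 73.0, 52.2 and 49.5 in normal brain replicates 1 to 3 and 59.8, 65.0, 57.3 and 50.9 in GL261 replicates 1 to 4. The group means were 58.2 ± 12.8 (SD, n = 3) and 58.3 ± 5.83 (SD, n = 4), with a two-sided exact permutation p of 1. The ratio of the 3' to the 5' probe set of Gapdh, a sign of RNA integrity and labelling length, was 2.41 ± 0.0243 (SD, n = 3) in normal brain and 1.75 ± 0.127 (SD, n = 4) in GL261. That difference had an exact permutation p of 0.0286, the smallest that the 35 splits of 7 arrays allow. The same ratio for actin was 1.57 ± 0.116 (SD, n = 3) and 1.42 ± 0.0715 (SD, n = 4), with an exact permutation p of 0.143. Correlations between arrays across the tested genes, which are not independent replicates, were 0.942 to 0.954 within GL261, 0.896 to 0.927 within normal brain and 0.875 to 0.922 between the groups. The highest correlation between the groups, 0.922, was that of GL261 replicate 2 with normal brain replicate 1.

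The comparison of GL261 with normal brain addressed how macrophages in this glioma differ in expression from those in normal brain. Of the genes tested, 11 of 22 matrix and protease, 14 of 27 interferon-response, 9 of 34 cell cycle and 5 of 14 glycolysis genes were called higher in the GL261 preparations. These 4 lists were called up by camera, and no call held with an estimated correlation between genes (adjusted p = 0.0765, 0.123, 0.225 and 0.164). Lists of oligodendrocyte precursor, pericyte and T and NK cell genes were called up as well (median log2 fold changes 1.81, 1.37 and 0.89), again not with an estimated correlation. Called lower were 9 of 18 homeostatic microglia, 9 of 14 border-associated macrophage, 7 of 8 B and plasma cell, 6 of 11 neutrophil and 5 of 13 endothelial genes. Those 5 lists were called down, and no call held with an estimated correlation (adjusted p = 0.0765, 0.0765, 0.0765, 0.127 and 0.248). Which cells of the preparations carried the higher or lower values was not determined. The groups may also differ in which macrophages the GFP sort took. Single genes called higher included the complement activator Cfb, the arginine-degrading enzyme Arg1 and the collagenase Mmp13, and those called lower included P2ry12, Ms4a1 and Ngp. Cfb, at log2 8.16 ± 0.43 (SD, n = 3) in normal brain and 12.68 ± 0.31 (SD, n = 4) in GL261, was 22.9-fold higher (adjusted p = 2.58e-06). P2ry12, a purinergic receptor of microglia, fell by 1.28 on the log2 scale (SE 0.25, adjusted p = 0.00913). The sorting marker Adgre1, which encodes F4/80, had a log2 fold change of -0.39 that was not called (SE 0.13, adjusted p = 0.0814) and was at 12.61 ± 0.07 (SD, n = 4) in GL261.

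In all, 1227 of the 12125 genes (10.1%) were called at an adjusted p under 0.05, 718 higher and 509 lower in GL261, and 721 of them changed at least 2-fold (450 higher, 271 lower). The groups did not overlap for 1195 of the called genes. Over all tested genes, 2841 (23.4%) had groups without overlap, against 5.71% by chance. The higher share was 58.5% of the called genes as deposited and 47.1% when each array was centred on its median, so which direction held more called genes depended on the scaling. The count was 542 without GL261 replicate 3, 722 without GL261 replicate 1 and 730 without GL261 replicate 4, and at least 2-fold changes numbered 390 without GL261 replicate 3. Genes called higher numbered 403, 305 and 414 without GL261 replicates 1, 3 and 4. Genes called lower numbered 323 and 319 without normal brain replicates 2 and 3, and 319, 237 and 316 without GL261 replicates 1, 3 and 4. With at least 2-fold changes 241 were higher and 149 lower without GL261 replicate 3, and 293 were higher without GL261 replicate 1. With a variance model that does not follow the mean signal, 455 genes were called. Of the 137 named genes that were called, 46 lost their call in some fit without 1 array and 62 under that variance model.

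Of the genes with the largest increases, Adamdec1, a metalloproteinase of the ADAM family, had a log2 fold change of 7.91 (SE 0.98, adjusted p = 0.000874) and was above background on 1 of the 3 normal brain arrays. Saa3, an acute-phase serum amyloid gene, rose by 5.41 (SE 0.75, adjusted p = 0.00148) and Arg1 by 5.28 (SE 0.78, adjusted p = 0.00243), the latter from 6.70 ± 1.66 (SD, n = 3) to 11.98 ± 1.44 (SD, n = 4). Sox10, a transcription factor of the oligodendrocyte lineage, rose by 5.16 (SE 0.60, adjusted p = 0.000551) and the cadherin Fat1 by 4.76 (SE 0.46, adjusted p = 0.000224). The granzyme Gzmc rose by 4.62 (SE 0.61, adjusted p = 0.00125) and the protease inhibitor Serpina3n by 4.51 (SE 0.62, adjusted p = 0.00146). Saa3 was above background on 2 of the 3 normal brain arrays, and Sox10 and Serpina3n on 1 each. For genes at background on all 3 normal brain arrays only lower bounds against the background can be given. They take the GL261 mean as exact and are not confidence limits. Moxd1, a monooxygenase-like gene, was at least 36.7-fold higher (adjusted p = 0.000142), and the cartilage-type collagen genes Col9a1 and Col11a1 at least 21.2-fold (adjusted p = 0.000224) and 10.4-fold higher (adjusted p = 0.000275). The granzyme Gzmg was at least 20.2-fold higher by this bound (adjusted p = 0.0101), and its call was lost when the variance model did not follow the signal. The 95% confidence interval of its fitted log2 fold change was 3.32 to 8.36. GL261 replicate 2 had the lowest GL261 value of Adamdec1 (9.38, others 12.77 to 12.78), Arg1 (9.83), Gzmc (10.35) and Gzmg (4.80).

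Of the genes with the largest decreases, the immunoglobulin kappa gene Igk-V21 fell by 6.43 on the log2 scale (SE 0.63, adjusted p = 0.000224). Another pair of kappa variable segments, with gene IDs 434025 and 545847, fell by 5.52 (SE 0.52, adjusted p = 0.000224) and decreased by 4.41 (SE 0.51, adjusted p = 0.000551). Another probe set of gene 434025 was at -0.04 (adjusted p = 0.989). Growth hormone (Gh) fell by 6.02 (SE 0.41, adjusted p = 3.58e-05), from 11.25 ± 0.18 (SD, n = 3) to 5.23 ± 0.45 (SD, n = 4). Transthyretin (Ttr), a transport protein of choroid plexus and liver, fell by 5.97 (SE 0.51, adjusted p = 0.000131). The haemoglobin gene Hbb-b2 fell by 5.40 (SE 1.04, adjusted p = 0.00902), and its GL261 values were 12.03 in replicate 2 and 6.16 to 7.54 in the others. Alas2, a haem synthesis gene of red cells, fell by 4.85 (SE 1.09, adjusted p = 0.0175), and the caveolar gene Cavin2 fell by 5.21 (SE 0.75, adjusted p = 0.00209), with -1.501 in another probe set that was not called (adjusted p = 0.130). Prom1, a stem cell membrane protein gene, fell by 4.88 (SE 0.87, adjusted p = 0.00617), the transporter gene Slco1a4 fell by 4.69 (SE 0.95, adjusted p = 0.0111), and Sema3c fell by 4.24 (SE 0.82, adjusted p = 0.00913). The neutrophil granule gene Ngp fell by 4.66 (SE 0.77, adjusted p = 0.0043). Among the 4 GL261 arrays, Ttr was above background on 3, Slco1a4 and the kappa segment with gene ID 434025 on 2, and Igk-V21, the kappa segment with gene ID 545847, Cavin2, Prom1, Alas2 and Sema3c on 1. Hbb-b2, Alas2 and Slco1a4 lost their calls under the variance model that does not follow the signal, and Alas2 also in 3 of the 7 fits without 1 array (adjusted p up to 0.0590, without GL261 replicate 3).

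**Figure D1:**
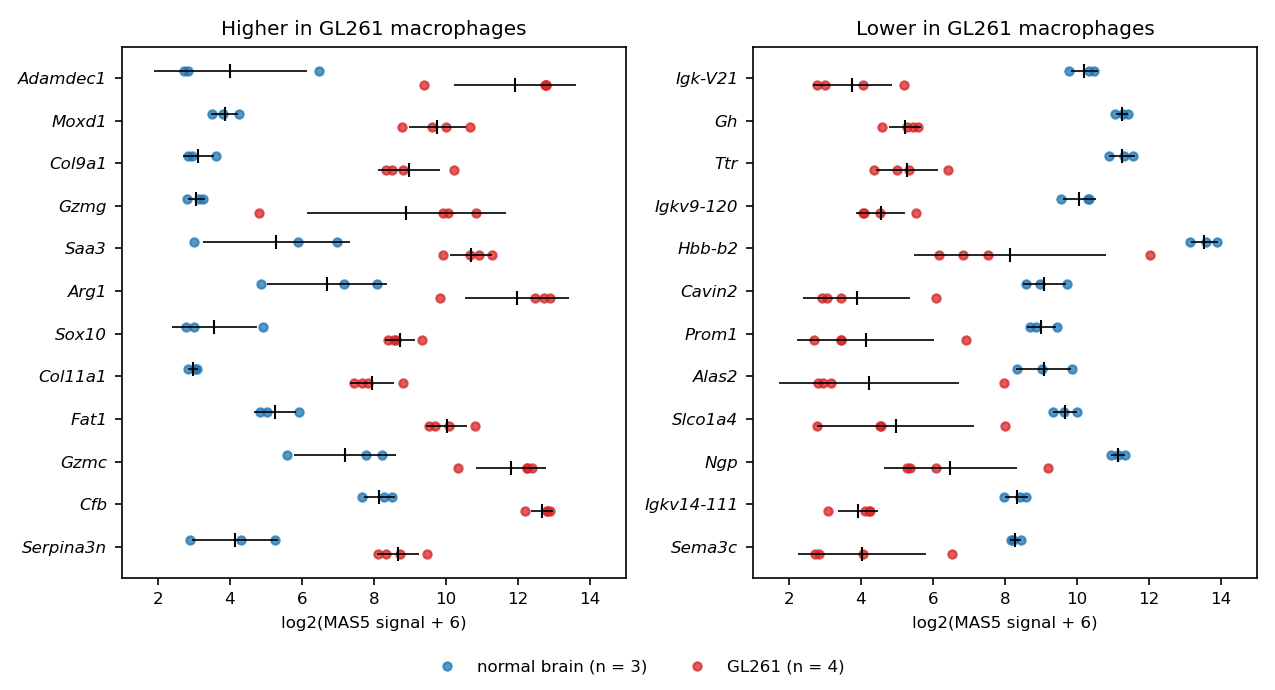
The 12 genes with the largest increase and the 12 with the largest decrease in GL261, as log2(MAS5 signal + 6) per array, with points for single arrays of normal brain (n = 3) and GL261 (n = 4) and a black tick and line for the mean and SD. The groups do not overlap for any of the 24 genes, and GL261 replicate 2 lies nearest the normal brain values for Adamdec1, Hbb-b2 and Alas2.

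The 2 lists of resident brain macrophage genes were called down in GL261, though not with an estimated correlation. Cells were sorted by GFP, and the tumour-bearing mice carried GFP-labelled marrow, which is not known for the normal brain mice. The decreases therefore cannot be told apart from a difference between the groups in which macrophages were sorted. Of 18 tested homeostatic microglia genes 9 fell and 0 rose, and 12 were lower when adjusted over the list alone (median log2 fold change -0.60). The list was called down (camera adjusted p = 4.23e-09, range 9.89e-11 to 0.0765 over 22 alternatives), with adjusted p = 0.0765 with an estimated correlation. Siglech, a sialic acid-binding lectin, fell by 2.00, the receptor gene Gpr34 fell by 1.82 and Golm1 fell by 1.56. The fractalkine receptor Cx3cr1 fell by 0.71 (adjusted p = 0.0270) and Tmem119 fell by 0.61 (adjusted p = 0.0252). Of 14 border-associated macrophage genes 9 fell and 1 rose (median -0.95), and 9 were lower and 2 higher when adjusted over the list alone. That list was also called down (camera adjusted p = 0.000175, range 1.46e-05 to 0.0765), with adjusted p = 0.0765 with an estimated correlation. The haemoglobin scavenger receptor Cd163 fell by 1.82, Igfbp4 fell by 1.79, Cbr2 fell by 1.40 and the mannose receptor Mrc1 fell by 0.69, while the lectin gene Clec4n rose by 1.14. Of the other Igfbp4 probe sets 2, at -0.45 and -0.51, were not called. Lower members numbered 5 of the microglia list without normal brain replicate 3, and 5 of the border-associated list without normal brain replicate 2, GL261 replicate 1 or GL261 replicate 3. Calls were lost in fits without 1 array for Golm1 (2 of 7 fits, adjusted p up to 0.0521 without GL261 replicate 3), Cx3cr1 (4 fits, 0.0863 without normal brain replicate 3), Tmem119 (5 fits, 0.0773 without normal brain replicate 3), Cd163 (5 fits, 0.0783 without normal brain replicate 1), Cbr2 (6 fits, 0.100 without normal brain replicate 1) and Mrc1 (6 fits, 0.129 without normal brain replicate 3).

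The monocyte and general macrophage lists were not called in the values as deposited. Of 19 tested monocyte and recruited macrophage genes 5 rose and 1 fell, and 5 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.412). The list's median log2 fold change was 0.02, -0.07 under median centring and -0.11 to 0.14 without 1 array. With every probe set tested by itself the list was called up (median 0.15, adjusted p = 0.0433, range 0.0433 to 0.929). Without GL261 replicate 2, 2 of its genes were called lower. The coagulation factor F10 rose by 2.41, fibronectin (Fn1) by 1.31 (0.87 without normal brain replicate 2) and guanine deaminase (Gda) by 1.21, while the monocyte chemokine receptor Ccr2 fell by 0.63 (adjusted p = 0.0299). Of 16 pan-macrophage and leukocyte genes 1 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.754). Their median was -0.13 (-0.20 to -0.04 without 1 array) and their mean 0.06, the camera direction was down, and under quantile normalization the median was 0.11 and the list was called up (adjusted p = 0.0310, range 0.0310 to 0.979 over 22 alternatives). The gene that rose was Mertk, a receptor for apoptotic cells, by 1.06. Itgam (0.88, adjusted p = 0.312, or 0.52 without normal brain replicate 3 and 1.44 without normal brain replicate 1), Ptprc (-0.36, adjusted p = 0.163) and Csf1r (-0.28, adjusted p = 0.394, or -0.15 without normal brain replicate 3 and -0.17 without GL261 replicate 2) were not called. Fits without 1 array lost the calls of Ccr2 (5 of 7, adjusted p up to 0.0965 without normal brain replicate 3) and Mertk (5 of 7, up to 0.0757 without GL261 replicate 3). Mertk was lowest in GL261 replicate 2 (11.31).

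The lists of B cell, neutrophil, red cell and vessel genes were called down in GL261, though not with an estimated correlation. All 8 tested B and plasma cell genes had lower values and 7 fell, 8 when adjusted over the list alone (median -2.16). This list was called down (camera adjusted p = 1.18e-08, range 1.97e-10 to 0.0765), with adjusted p = 0.0765 with an estimated correlation. The B cell surface gene Ms4a1 (CD20) fell by 3.73, the antigen receptor chain Cd79a fell by 3.64 and the kinase gene Blk fell by 3.43. Of 11 neutrophil genes 6 fell and 0 rose, 8 lower when adjusted over the list alone (median -1.01, camera adjusted p = 2.01e-06, range 4.92e-08 to 0.127), with adjusted p = 0.127 with an estimated correlation. Besides Ngp, the granule genes Mpo and Camp fell by 3.84 and decreased by 3.78. Of 13 endothelial genes 5 fell and 0 rose, and 10 were lower and 1 higher when adjusted over the list alone (median -2.32). The endothelial list was called down (camera adjusted p = 2.03e-05, range 2.72e-08 to 0.248), with adjusted p = 0.248 with an estimated correlation. The angiopoietin receptor Tek fell by 4.04 and the tight junction gene Cldn5 fell by 3.69. Of 4 erythroid genes Hbb-b2 and Alas2 fell, also when adjusted over the list alone, and the list (median -3.12) was called down (camera adjusted p = 0.0232, range 5.7e-05 to 0.333), with adjusted p = 0.333 with an estimated correlation.

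GL261 replicate 2 stood apart from the other GL261 arrays in these blood and vessel genes. Relative to the mean of all 7 arrays, the endothelial genes averaged 0.38 in replicate 2 and -1.34 to -1.20 in the other GL261 arrays, the neutrophil genes 0.19 against -1.29 to -0.90, and the erythroid genes 1.14 against -2.30 to -1.84. Without replicate 2, 7 endothelial, 6 neutrophil and 6 B cell genes were called lower. Endothelial genes called lower numbered 2 without GL261 replicate 1, 3 or 4 and 3 without any of the normal brain replicates. Erythroid genes called lower numbered 1 without normal brain replicate 3, GL261 replicate 3 or GL261 replicate 4. The erythroid list was not called in 7 of 21 alternatives, among them the fits without normal brain replicate 2 (adjusted p = 0.146) or GL261 replicate 1 (adjusted p = 0.0551). Its median was -0.70 without a filter (adjusted p = 0.0964) and -0.63 with every probe set tested by itself (adjusted p = 0.104), and it was not called in either. The endothelial median was -1.43 with a filter at the 60th percentile, where the list was called (adjusted p = 0.00144). With a pseudocount of 58 the medians were -1.41 for B cell, -1.33 for endothelial and -1.72 for erythroid genes, and these lists were called. Cldn5 lost its call in 5 of the 7 fits without 1 array (adjusted p up to 0.0632 without GL261 replicate 3). On the GL261 arrays, Mpo, Blk and Tek were above background on 2 of 4.

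**Figure D2:**
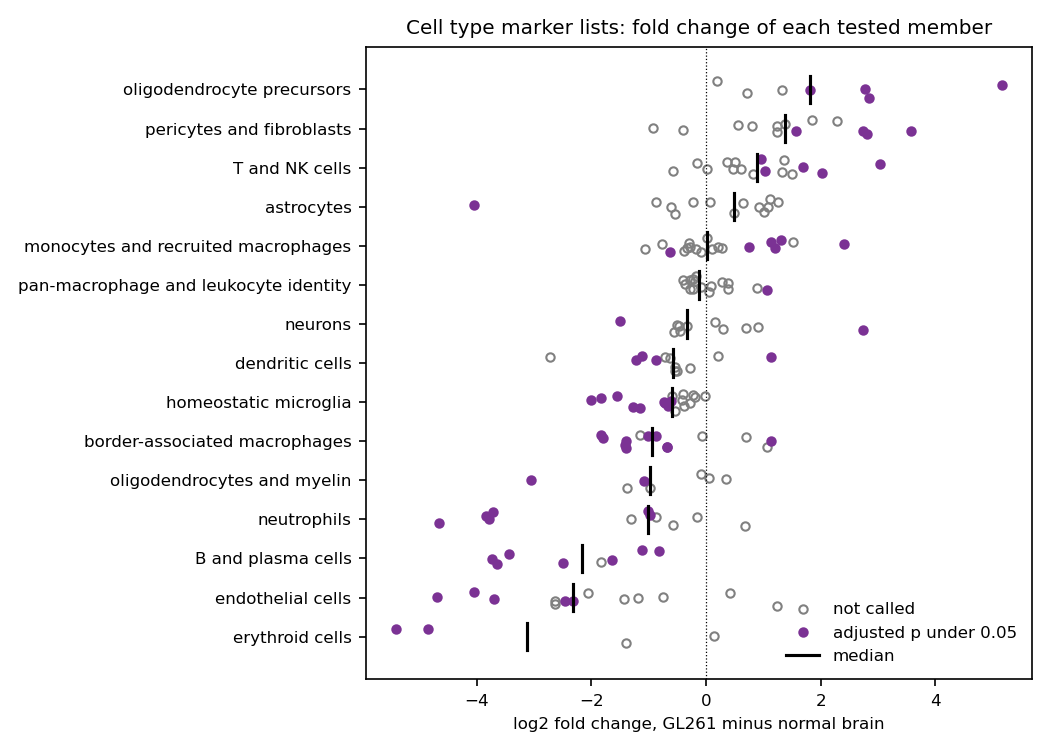
The log2 fold change of each tested member of the 15 cell type lists that had a group test, GL261 minus normal brain, with purple points for genes at an adjusted p under 0.05, open points for genes not called and a black bar for the list's median. B cell, endothelial and erythroid members lie mostly below 0 and oligodendrocyte precursor and pericyte members mostly above it.

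The oligodendrocyte precursor, pericyte and T and NK cell lists were called up in GL261, though not with an estimated correlation. Of 7 oligodendrocyte precursor genes 4 rose and 0 fell, also when adjusted over the list alone (median 1.81, or 1.32 with genes at background set to their lower bound). The list was called up (camera adjusted p = 0.000978, range 1.34e-05 to 0.113), with adjusted p = 0.113 with an estimated correlation. With a pseudocount of 58 the precursor median was 0.76 and the pericyte median 0.65, and both lists were called. Besides Sox10, the transcription factor gene Olig1 rose by 2.77, and Olig2, at background on all normal brain arrays, was at least 3.70-fold higher. Of 13 pericyte and fibroblast genes 4 rose and 0 fell, 8 higher when adjusted over the list alone (median 1.37, or 1.25 with the bounds). That list was called up (camera adjusted p = 0.000978, range 7.94e-05 to 0.248), with adjusted p = 0.248 with an estimated correlation and 0.0602 with a filter at the 60th percentile. The fibrillar collagen genes Col3a1 and Col1a1 rose by 3.58 and 2.73 and the actin-binding Tagln by 2.81. Pericyte members called numbered 1 without GL261 replicate 2 or 3 and 2 without GL261 replicate 1, GL261 replicate 4 or normal brain replicate 1. Of 16 T and NK cell genes 5 rose and 0 fell, 7 higher when adjusted over the list alone (median 0.89, camera adjusted p = 0.00131, range 9.08e-05 to 0.278), with adjusted p = 0.278 with an estimated correlation. The co-receptor genes Cd8a and Cd8b1 rose by 3.03 and 2.02 and the granzyme Gzmb by 1.69, and another Cd8a probe set, at 1.498, was not called (adjusted p = 0.160). T and NK members called numbered 2 without GL261 replicate 3 or 4 and 3 without GL261 replicate 1. Cd8b1 was above background on 1 and Tagln on 2 of the 3 normal brain arrays. Fits without 1 array lost the calls of Tagln (4 of 7, adjusted p up to 0.0804 without GL261 replicate 3), Col1a1 (6 of 7, 0.0910 without GL261 replicate 1, and a log2 fold change of 1.70 without normal brain replicate 1) and Cd8b1 (6 of 7, 0.0974 without GL261 replicate 3).

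The dendritic cell and myelin lists were called down, though not with an estimated correlation. Of 12 dendritic cell genes 3 fell and 1 rose, 6 lower and 1 higher when adjusted over the list alone (median -0.58, camera adjusted p = 0.00391, range 0.000143 to 0.278), with adjusted p = 0.278 with an estimated correlation and 0.0756 by fry. The transcription factor Irf4 fell by 1.22, the cytokine receptor Flt3 fell by 1.12 and Dpp4 fell by 0.87, while the integrin Itgax (CD11c) rose by 1.13. Dendritic members called lower numbered 1 without normal brain replicate 2 or GL261 replicate 4. Of 7 oligodendrocyte and myelin genes 2 fell and 0 rose, also when adjusted over the list alone: Mal fell by 3.05 and the myelin protein gene Mbp fell by 1.07. This list (median -0.97) was called down (camera adjusted p = 0.0376, range 0.000471 to 0.289), with adjusted p = 0.289 with an estimated correlation, and was not called in 13 of 22 alternatives. Among these were the fits without normal brain replicate 2 (0.144), normal brain replicate 3 (0.0633), GL261 replicate 1 (0.0594) or GL261 replicate 2 (0.0799) and the fit under median centring (0.0557). The myelin median was -0.41 without normal brain replicate 2, -0.16 without a filter (0.110), -0.49 with a pseudocount of 58 (0.0918) and -0.59 with the hybridisation control level in the model (0.0963). Its lower members numbered 1 without normal brain replicate 1 or GL261 replicate 2 and 0 without normal brain replicate 2 or 3 or GL261 replicate 1 or 4. Another probe set of Mbp had a log2 fold change of 0.48 that was not called (adjusted p = 0.697).

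Neuron, astrocyte and choroid plexus lists were not called or not tested as groups. Of 11 neuron genes 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.774): the tubulin gene Tubb3 rose by 2.74 and the enolase gene Eno2 fell by 1.49. The neuron median was -0.34, the mean 0.09 and the camera direction down, and the median was 0.07 without normal brain replicate 2, 0.02 without GL261 replicate 1 or GL261 replicate 2, and 0.16 with a filter at the 60th percentile. Of 13 astrocyte genes the thyroid hormone transporter gene Slco1c1 fell by 4.05 and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.988, with direction down beside a median of 0.48 and a mean of 0.02). The GL261 values of Slco1c1 were 9.43 in replicate 2 and 4.04 to 6.94 in the others, and the endothelial list was likewise highest in replicate 2 among the GL261 arrays. The astrocyte median was 0.15 without normal brain replicate 1, 0.18 without normal brain replicate 3, 0.23 without GL261 replicate 3 and 0.78 without GL261 replicate 2. Of the ependyma and choroid plexus genes 2 were tested, too few for a group test, and while Ttr fell, the water channel gene Aqp1 rose by 3.52. Of the sex-linked genes, Xist, the RNA of the inactive X chromosome, was tested and fell by 0.67 (adjusted p = 0.0302), and the Y-linked Kdm5d, Eif2s3y and Uty were below the filter, while Ddx3y had no probe set with 1 symbol. Tubb3 and Aqp1 were above background on 1 of the 3 normal brain arrays, and Mal on 2 and Slco1c1 on 3 of the 4 GL261 arrays. Fits without 1 array lost the calls of Mal (5 of 7, adjusted p up to 0.0974 without normal brain replicate 3), Mbp (5 of 7, 0.0917 without normal brain replicate 2), Eno2 (5 of 7, 0.156 without normal brain replicate 3), Tubb3 (4 of 7, 0.0773 without normal brain replicate 2), Xist (5 of 7, 0.0975 without normal brain replicate 3), Flt3 (5 of 7, 0.0692 without normal brain replicate 1) and Dpp4 (4 of 7, 0.0731 without normal brain replicate 2).

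Called macrophage activation genes split between the directions, while the called interferon-response genes rose. Of 17 classical (M1) genes 2 rose and 2 fell, 3 higher and 2 lower when adjusted over the list alone (median 0.24, camera adjusted p = 0.335). The interferon-induced chemokines Cxcl9 and Cxcl10 rose by 2.93 and 0.92, and the cytokine Tnf fell by 1.25. Nos2 was below the filter and not tested. Of 23 alternative (M2) genes 4 rose and 7 fell, 9 higher and 11 lower when adjusted over the list alone (camera adjusted p = 0.805). Beside Arg1, which rose, the resistin-like Retnla fell by 2.60, the chemokine Ccl22 fell by 1.86 and the anti-inflammatory cytokine Il10 fell by 1.83. The M2 median was 0.44 (0.25 without normal brain replicate 3), the mean 0.03 and the camera direction down, and with every probe set tested by itself the list was called up (median 0.50, adjusted p = 0.0497, range 0.0497 to 0.989). Without GL261 replicate 2, 7 M2 genes were called higher, and without normal brain replicate 3, 1 M1 gene was called lower. Of 27 interferon-response genes 14 rose and 0 fell, 20 higher when adjusted over the list alone (median 0.80). The list was called up (camera adjusted p = 9.28e-10, range 3.53e-14 to 0.123), with adjusted p = 0.123 with an estimated correlation. The guanylate-binding protein Gbp2 rose by 2.43, Oasl1 by 1.67 and Ifit2 by 1.65.

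The MHC class II and early-response lists were called down and the checkpoint and suppression list up, though not with an estimated correlation, and the MHC class I list was not called in the values as deposited. Of 9 MHC class II genes 2 fell and 0 rose, 3 lower when adjusted over the list alone (median -0.29). The list was called down (camera adjusted p = 0.00244, range 1.57e-06 to 0.278), with adjusted p = 0.278 with an estimated correlation, and under quantile normalization its median was 0.02 and it was not called (0.105). Its median was -0.16 without normal brain replicate 3, -0.19 without GL261 replicate 1 and -0.17 without GL261 replicate 2. H2-Ob fell by 2.22 and H2-Oa fell by 1.01, and both encode chains of an inhibitor of peptide loading. The other 7 class II genes were not called. Whether the decreases lay in macrophages or in B cells, whose genes were also lower in GL261, was not tested. Of 11 MHC class I genes the peptide transporter gene Tap1 rose by 0.69 and 0 fell, also when adjusted over the list alone (median 0.16, camera adjusted p = 0.417). Without 1 array the class I median was 0.02 (normal brain replicate 2) to 0.28 (normal brain replicate 3), and it was -0.04 with every probe set tested by itself. The class I list was called up under quantile normalization (adjusted p = 0.00588) and with the hybridisation control level in the model (0.0158, range 0.00588 to 0.943). The Tap1 call was lost without GL261 replicate 3 (adjusted p = 0.0555), and another of its probe sets had a log2 fold change of -0.48 that was not called (adjusted p = 0.611). Of 18 immune checkpoint and suppression genes 7 rose and 1 fell, 11 higher and 2 lower when adjusted over the list alone (median 0.57, camera adjusted p = 0.00361, range 0.00012 to 0.235), with adjusted p = 0.235 with an estimated correlation. Besides Arg1, the ectonucleotidase gene Nt5e (CD73) rose by 2.35 and the checkpoint ligand Cd276 by 1.73, while Il10 fell. Nt5e was above background on 2 of the 3 normal brain arrays. Checkpoint members called higher numbered 3 without GL261 replicate 1 or 3. The calls of Nt5e (6 of 7 fits, adjusted p up to 0.110 without GL261 replicate 3, and a log2 fold change of 1.47 without normal brain replicate 2) and Cd276 (3 of 7, 0.0732 without GL261 replicate 4) were lost in fits without 1 array. Of 20 immediate early and dissociation-response genes 9 fell and 0 rose, 14 lower when adjusted over the list alone (median -0.56, camera adjusted p = 2.3e-09, range 3.99e-15 to 0.248), with adjusted p = 0.248 with an estimated correlation. The transcription factors Egr3 and Jun fell by 1.64 and decreased by 1.25, and the heat shock gene Hspa1a fell by 1.07. Early-response members called lower numbered 5 without normal brain replicate 3.

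Among signalling groups the NF-kB list was called down, though not with an estimated correlation, and the chemokine, cytokine and receptor lists were called in some alternatives. Of 17 NF-kB genes 3 fell and 1 rose, 7 lower and 1 higher when adjusted over the list alone (median -0.41, camera adjusted p = 0.000638, range 1.09e-06 to 0.248), with adjusted p = 0.248 with an estimated correlation. The pathway's Nfkbiz, Rel and Relb fell by 0.98, decreased by 0.84 and decreased by 0.73, while superoxide dismutase Sod2 rose by 0.92 (0.38 in another probe set that was not called), and 1 member was called lower without normal brain replicate 1 or GL261 replicate 3. Of 25 chemokine ligands 3 rose and 8 fell, 4 higher and 11 lower when adjusted over the list alone (camera adjusted p = 0.139). Their median was -0.0048, their mean 0.0046 and the camera direction down, with a median of 0.06 under quantile normalization and of -0.26 (normal brain replicate 3) to 0.14 (GL261 replicate 2) without 1 array. Besides Ccl22 and Cxcl9, the monocyte attractant Ccl2 fell by 1.29 and the neutrophil attractant Cxcl1 fell by 1.33. Without GL261 replicate 3 or 4 the ligand list was called down (adjusted p = 0.0356 and 0.0388, range 0.0115 to 0.700 over 22 alternatives), without GL261 replicate 2 its higher members numbered 5, and its lower members numbered 3 without normal brain replicate 3 and 5 without normal brain replicate 2, GL261 replicate 1 or GL261 replicate 2. Of 17 chemokine and myeloid growth factor receptors 2 rose and 4 fell, also when adjusted over the list alone (median -0.28, camera adjusted p = 0.0965). With every probe set tested by itself the receptor list was called down (0.00511), as it was by fry (0.0428, range 0.00511 to 0.289), and its median was -0.15 without normal brain replicate 3 and -0.17 without GL261 replicate 2. Cxcr6 fell by 2.24 and Cxcr3 fell by 1.81, both receptors of lymphocytes, and Csf2rb2 rose by 1.27 (0.84 without normal brain replicate 2). Receptor members called lower numbered 1 without GL261 replicate 4 and 2 without any normal brain replicate or GL261 replicate 1 or 3, and 1 was higher without normal brain replicate 3 or GL261 replicate 1, 3 or 4.

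Of 21 interleukin and TNF-family genes 2 rose and 4 fell, 3 higher and 6 lower when adjusted over the list alone (median -0.29, camera adjusted p = 0.0517). The cytokine Lif fell by 2.61 and Tnfsf9 fell by 1.37, and Il18bp, a decoy receptor for interleukin 18, rose by 2.95. This list was called down in 6 of 22 alternatives, among them those without normal brain replicate 2 (0.0192), GL261 replicate 3 (0.0356) or GL261 replicate 4 (0.0409), with a range of adjusted p of 0.0192 to 0.653. Its median was -0.58 without normal brain replicate 2 and -0.43 without GL261 replicate 3. Of 18 toll-like receptor and signalling genes Tlr13 rose by 0.79 and Tlr2 fell by 0.62, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.417), and 2 were called higher without normal brain replicate 1. The median was -0.16 without GL261 replicate 3 and 0.07 with every probe set tested by itself. Of 18 TGF-beta pathway genes 3 fell and 0 rose, 6 lower and 4 higher when adjusted over the list alone (camera adjusted p = 0.175). The ligand Tgfb2, above background on 2 of the 4 GL261 arrays, fell by 2.59, the inhibitor Smad7 fell by 0.65 and the receptor Tgfbr2 fell by 0.64. The TGF-beta median was -0.22, the mean 0.04 and the camera direction down, and 1 member was called lower without normal brain replicate 3. Members called higher numbered 2 without normal brain replicate 1 and 1 without GL261 replicate 4. Another probe set of Tgfbr2 was at 0.02 (adjusted p = 0.993), and other Tgfb2 probe sets were at -0.21 (adjusted p = 0.853) and -0.37 (adjusted p = 0.783). Calls lost in fits without 1 array among the signalling genes were those of Tgfb2 (5 of 7, adjusted p up to 0.108 without GL261 replicate 3), Smad7 (2 of 7, 0.0588 without normal brain replicate 3), Tlr2 (5 of 7, 0.0580 without normal brain replicate 2), Rel (3 of 7, 0.0585 without GL261 replicate 3), Relb (5 of 7, 0.0723 without GL261 replicate 1), Cxcl1 (6 of 7, 0.118 without normal brain replicate 3), Cxcr6 (5 of 7, 0.0789 without normal brain replicate 1) and Csf2rb2 (3 of 7, 0.0625 without GL261 replicate 3).

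The hypoxia, glycolysis and lipid-handling lists were called up in GL261, though not with an estimated correlation. Of 14 glycolysis genes 5 rose and 0 fell, 7 higher when adjusted over the list alone (median 0.55, camera adjusted p = 0.000175, range 2.63e-06 to 0.164), with adjusted p = 0.164 with an estimated correlation. The enzymes Tpi1 and Pfkl rose by 1.26 and 1.16 and the lactate exporter Slc16a3 by 1.07, though another probe set of Pfkl was called lower (-1.44, adjusted p = 0.0254). Gapdh, a listed glycolysis gene, had no probe set with 1 symbol and was not among the tested genes. Of 22 hypoxia genes 6 rose and 0 fell, 9 higher and 1 lower when adjusted over the list alone (median 0.46, camera adjusted p = 0.0179, range 0.000394 to 0.235), with adjusted p = 0.235 with an estimated correlation. The mitophagy gene Bnip3 rose by 1.25, the kinase gene Pdk1 by 1.10 and lactate dehydrogenase Ldha by 0.91. Another Pdk1 probe set had a log2 fold change of -0.68 that was not called (adjusted p = 0.437). Without normal brain replicate 1 the hypoxia list was not called (0.105), and its median was 0.30 without normal brain replicate 2. Its called members numbered 2 without GL261 replicate 1 or 3 and 3 without GL261 replicate 4 or normal brain replicate 2. Of 18 lipid handling and cholesterol efflux genes 6 rose and 0 fell, 7 higher and 1 lower when adjusted over the list alone (median 0.43, camera adjusted p = 0.0191, range 0.000643 to 0.173), with adjusted p = 0.173 with an estimated correlation, 0.0534 with the replicate block and 0.0536 without normal brain replicate 1. The liver X receptor gene Nr1h3 rose by 1.83, and the scavenger receptor Cd36 and the glycoprotein gene Gpnmb each by 1.42. Another Cd36 probe set, at 0.27, was not called (adjusted p = 0.828). Lipid members called numbered 2 without normal brain replicate 2 or GL261 replicate 3 and 3 without GL261 replicate 4.

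Of 27 oxidative phosphorylation genes 4 rose and 0 fell, 7 higher when adjusted over the list alone (median 0.15, camera adjusted p = 0.0232, range 7.18e-05 to 0.545), with adjusted p = 0.545 with an estimated correlation. The respiratory chain genes Sdhb and Uqcrc1 rose by 0.82 and 0.67 and the ATP synthase gene Atp5b by 0.55. This list was not called in 9 of 22 alternatives, among them median centring (0.104) and the fits without normal brain replicate 1 (0.277), GL261 replicate 3 (0.0738) or GL261 replicate 4 (0.0794), and its called members numbered 1 without GL261 replicate 3 and 2 without normal brain replicate 1, GL261 replicate 1 or GL261 replicate 4. The median was 0.06 under median centring, 0.08 without normal brain replicate 1, 0.10 without GL261 replicate 3, 0.08 without GL261 replicate 4 and 0.24 with every probe set tested by itself. Of 18 ribosomal protein genes limma called 0 higher and 0 lower, also when adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05, and the list was called down (median -0.27, camera adjusted p = 0.00377), with adjusted p = 0.573 with an estimated correlation. Under quantile normalization the ribosomal median was 0.04 (adjusted p = 0.989, range 2.07e-10 to 0.989), and the call was lost by fry (0.372) and without normal brain replicate 3 (0.104), GL261 replicate 1 (0.0594) or GL261 replicate 2 (0.0575), with medians of -0.13, -0.15 and -0.16. The ribosomal genes with the smallest p were Rps14 (-0.51, adjusted p = 0.164) and Rps18 (-0.48, adjusted p = 0.178). Of 17 cholesterol biosynthesis genes the mevalonate pathway gene Pmvk rose by 1.48 and 0 fell, also when adjusted over the list alone (median 0.12, camera adjusted p = 0.470), and fry called the list up (0.0174, range 0.0174 to 0.772), with a median of 0.05 without GL261 replicate 2 and 0.08 without normal brain replicate 1. Of 19 unfolded protein response genes 2 rose and 2 fell, 3 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.988, direction down beside a median of 0.28 and a mean of 0.23). Their median was -0.01 (normal brain replicate 3) to 0.25 (GL261 replicate 1) without 1 array, and it had the other sign in 4 of 22 alternatives. The disulfide isomerase gene Pdia4, above background on 2 of the 3 normal brain arrays, rose by 2.85 and Edem1 by 0.76, and the chaperone gene Dnajb9 fell by 0.58. Unfolded protein response members called higher numbered 0 without GL261 replicate 3 and 1 without normal brain replicate 2 or 3 or GL261 replicate 1 or 4, and those called lower 0 or 1 in every fit without 1 array. The calls of single genes of these metabolic groups lost in fits without 1 array were those of Pdk1 (3 of 7, adjusted p up to 0.0825 without GL261 replicate 3), Nr1h3 (4 of 7, 0.0664 without GL261 replicate 3), Cd36 (5 of 7, 0.0762 without GL261 replicate 3), Sdhb (1 of 7, 0.0523 without GL261 replicate 3), Atp5b (6 of 7, 0.0799 without GL261 replicate 3), Pdia4 (1 of 7, 0.0655 without GL261 replicate 3), Edem1 (5 of 7, 0.0657 without normal brain replicate 3) and Dnajb9 (5 of 7, 0.0967 without normal brain replicate 2).

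The matrix and protease and cell cycle lists were called up, though not with an estimated correlation. Of 22 tested matrix and protease genes 11 rose and 0 fell, 13 higher when adjusted over the list alone (median 0.91, camera adjusted p = 3.26e-07, range 1.49e-09 to 0.0765), with adjusted p = 0.0765 with an estimated correlation. Mmp13 rose by 4.51, the protease inhibitor Timp1 by 2.96 and the macrophage elastase Mmp12 by 2.16. Without normal brain replicate 3, 1 matrix and protease gene was called lower. Of 34 cell cycle genes 9 rose and 0 fell, 21 higher when adjusted over the list alone (median 1.22, camera adjusted p = 1.3e-09, range 8.17e-15 to 0.225), with adjusted p = 0.225 with an estimated correlation. The mitotic genes Ube2c and Tpx2 rose by 2.28 and 2.25 and the kinase Cdk1 by 1.92. Cell cycle members called numbered 5 without GL261 replicate 2 or 3, and relative to the mean of all arrays the list averaged 1.02 in GL261 replicate 2 and 0.16 to 0.57 in the other GL261 arrays. Of 21 lysosome and cathepsin genes 6 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.271). The proton pump subunit Atp6v0d2 rose by 3.70, the collagen-degrading cathepsin Ctsk by 2.98 and the cystatin gene Cst7 by 1.83. Ctsk was above background on 1 of the 3 normal brain arrays. The lysosome median was -0.06, the mean 0.48 and the camera direction up, and the median was 0.19 under quantile normalization, where the list was called (adjusted p = 4.08e-05, range 4.08e-05 to 0.802). It was called in 4 of 22 alternatives, also without normal brain replicate 3 (0.0429), and its median was above 0 in each of the 4 and -0.15 without GL261 replicate 4.

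Of 15 complement genes 4 rose and 1 fell, 6 higher and 1 lower when adjusted over the list alone (median 0.48, camera adjusted p = 0.153). Besides Cfb, the proteases C2 and C1s1 rose by 2.99 and 2.04, while Cd55, an inhibitor of complement, fell by 2.41. The complement list was called up in 5 of 22 alternatives, among them that without normal brain replicate 3 (0.0453, range 0.0141 to 0.738), and its higher members numbered 1 without normal brain replicate 2, GL261 replicate 3 or GL261 replicate 4 and 2 without normal brain replicate 1, GL261 replicate 1 or GL261 replicate 2. Of 18 Fc receptor and phagocytosis genes 5 rose and 2 fell, 7 higher and 2 lower when adjusted over the list alone (median 0.34, camera adjusted p = 0.114). This list was called up in 5 of 22 alternatives (range 0.000394 to 0.278): without a filter (0.0310), under quantile normalization (0.00926), with every probe set tested by itself (0.000394), by fry (0.0113) and with the hybridisation control level in the model (0.0444). Besides Cd36, the scavenger receptor Msr1 rose by 1.71 and the antibody receptor Fcgr4 by 1.67, while the bridging molecule Pros1 fell by 0.88. Phagocytosis members called higher numbered 2 without normal brain replicate 3, GL261 replicate 3 or GL261 replicate 4 and 3 without normal brain replicate 2, and those called lower 1 without normal brain replicate 2 or 3 or GL261 replicate 1, 3 or 4. Of 15 angiogenic and growth factor genes 2 rose and 2 fell, 4 higher and 2 lower when adjusted over the list alone (median 0.19, camera adjusted p = 0.853). Pdgfc rose by 2.90 and placental growth factor (Pgf) by 1.99, and Bmp2 fell by 3.13. Growth factor members called higher numbered 1 without normal brain replicate 3 or any GL261 replicate. Their median was -0.14 without normal brain replicate 2, -0.05 without GL261 replicate 2 and up to 0.47 without normal brain replicate 1. Of 20 integrin and adhesion genes 5 rose and 2 fell, 8 higher and 4 lower when adjusted over the list alone (median 0.15, camera adjusted p = 0.417), and fry called the list up (0.0272, range 0.0272 to 0.690). The vascular adhesion molecule Vcam1 rose by 1.54 and the integrin Itgal by 0.75, while Alcam fell by 1.13 (-0.23 in another probe set that was not called), and 3 members were called higher in each fit without 1 array. Members called lower numbered 0 without normal brain replicate 3 and 1 without normal brain replicate 2, GL261 replicate 1 or GL261 replicate 3. C2 and C1s1 were above background on 1 and Pgf on 2 of the 3 normal brain arrays. Other calls lost in such fits were those of C2 (6 of 7, adjusted p up to 0.124 without normal brain replicate 2), C1s1 (4 of 7, 0.0757 without GL261 replicate 3), Cd55 (4 of 7, 0.0737 without normal brain replicate 1), Pros1 (5 of 7, 0.0756 without normal brain replicate 2), Pgf (6 of 7, 0.130 without normal brain replicate 2), Tpx2 (4 of 7, 0.0961 without GL261 replicate 3) and Alcam (1 of 7, 0.0518 without normal brain replicate 3).

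**Figure D3:**
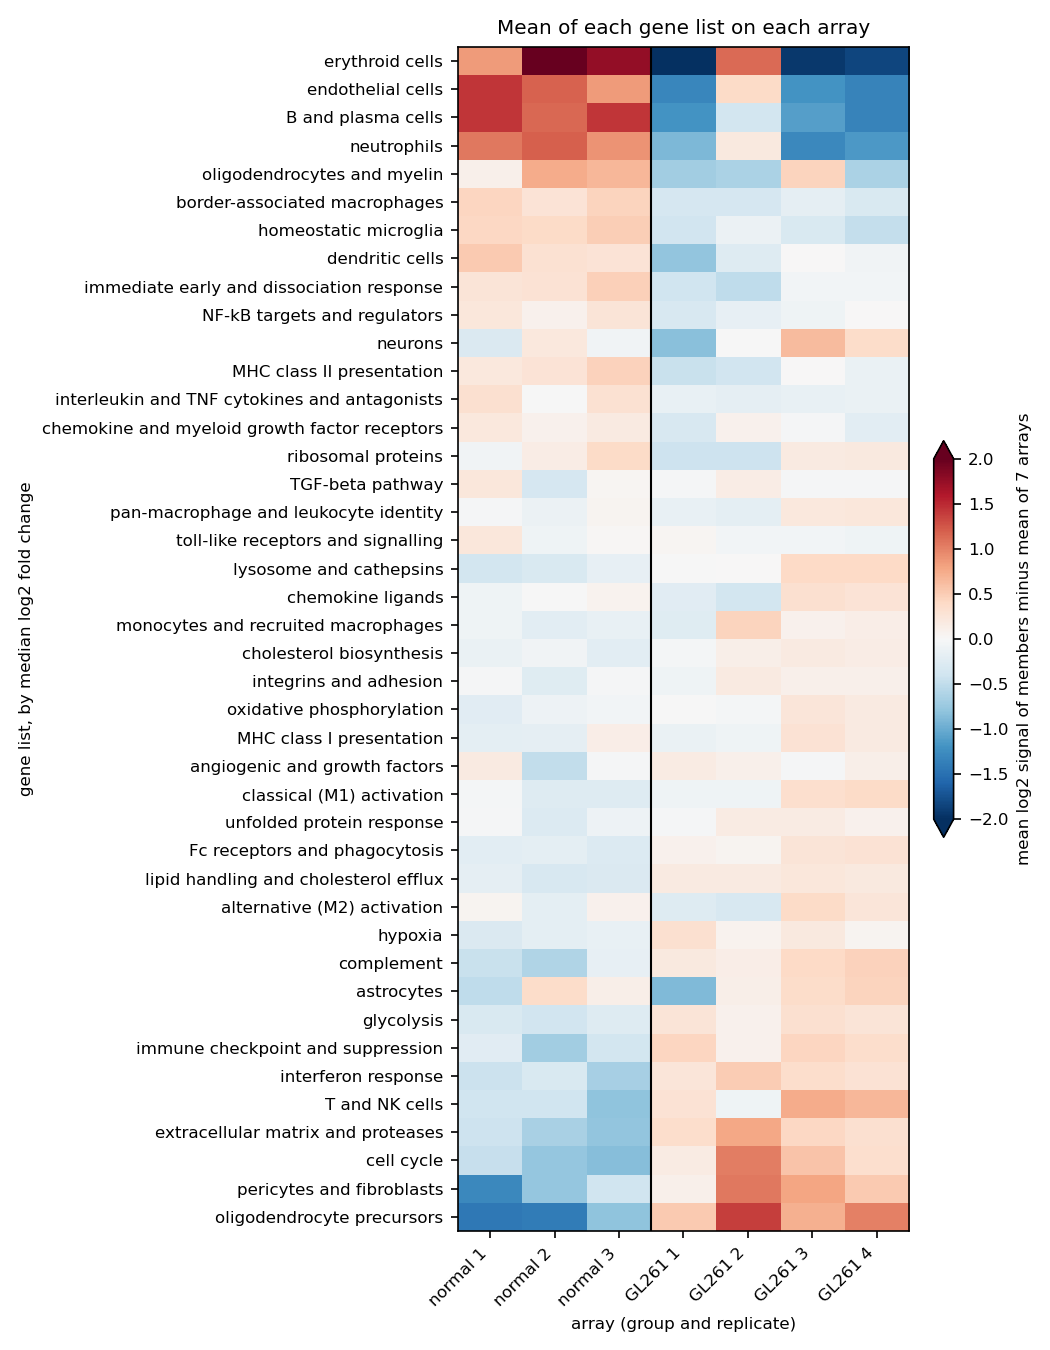
Mean log2 value of the tested members of 42 gene lists on each array, minus the mean of the 7 arrays, with lists ordered by median log2 fold change and colours clipped at 2 log2 units either way. Cell cycle, interferon and matrix lists are above the mean on the GL261 arrays, and the endothelial, neutrophil and erythroid lists are above it on the normal brain arrays and on GL261 replicate 2.

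Of the 44 lists, 42 had enough tested members for a group test and 23 were called, 11 up and 12 down. With an estimated correlation between genes camera called 0 lists, with 9 at an unadjusted p under 0.05, and the rotation test fry, which asks whether a list's genes move on balance in 1 direction, called 24.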

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

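The count over splits of the arrays was planned before its result was seen, and every other test in this part, that of array brightness included, was chosen after the data were seen.

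Within the 4 GL261 arrays, a single array lay far from the other values for 17 of the 143 named genes and 4 array measures examined, where chance flags about 1 in 20, or 7.4 here. In 16 of the 17 the array was GL261 replicate 2. Its log2 value was the lowest for Adamdec1 (9.38, others 12.77 to 12.78), Gzmg (4.80), Arg1 (9.83), Gzmc (10.35), Cfb (12.21), Gzmb (10.15), Mertk (11.31), Il18bp (10.59), Bnip3 (11.03), Mmp13 (10.31), Mmp12 (10.83) and Mrc1 (12.21). It was the highest for Cavin2 (6.09), Alas2 (7.98), Cldn5 (8.94) and Slc16a3 (10.94). The kappa segment with gene ID 545847 was lowest in GL261 replicate 4 (3.10).

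GL261 replicate 2 was the GL261 array nearest the normal brain arrays. It was not simply a mislabelled normal brain array, since its lowest correlation with a GL261 array (0.942) exceeded its highest with a normal brain array (0.922) by 0.0193. A uniform mixture with normal brain RNA as the whole source would give all genes 1 share. Replicate 2 held a median of 30.8% of the normal brain level for 12 vessel, blood and neutrophil genes. For 8 Gh, Ttr and immunoglobulin genes the median was 2.23%, a gap of 28.6 percentage points (exact permutation p over genes = 0.0298). The gene groups were picked after replicate 2 was seen to differ. That p treats co-varying genes of 1 array as independent, so it cannot decide the question. The shares varied within both gene groups, with 77.4% for Igha in the Gh, Ttr and immunoglobulin group. In the vessel, blood and neutrophil group they were -1.28% for Mpo, 7.67% for Tek and 8.54% for S100a8. Over all 271 genes called at least 2-fold lower the median share was 12.1%, and 79.7% of these genes had a share above 0. Yet replicate 2 was not nearest normal brain in every list. Relative to the mean of all arrays, it was the highest GL261 array for oligodendrocyte precursor (1.38, others 0.53 to 1.00) and pericyte genes (1.05, others 0.10 to 0.79). So it was for cell cycle (1.02, others 0.16 to 0.57) and matrix genes (0.77, others 0.32 to 0.42). T and NK genes went the other way (-0.09, others 0.28 to 0.75). More blood and vessel cells in this preparation may be a candidate explanation, and 76.5% of the endothelial and erythroid members (13 of 17) were highest in replicate 2. Selection by GFP and F4/80 is expected to reduce such cells, and how far it did so is not known. That share of members lies between what was set for and against it, the lists were chosen after the array was seen to differ, and with 1 such array it cannot be told apart from a difference between tumours, which was not tested.

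The number of called genes, 1227, was reached by 1 of the 35 splits of the arrays into 4 and 3, the real one, and the highest of the others called 149. That argues against chance but does not exclude it (exact permutation p = 0.0286, the smallest that 35 splits allow). The labels also do not state whether arrays came from separate mice. Array brightness is argued against by a hybridisation control level that was close in both groups. It was 12.80 ± 0.40 (SD, n = 3) in normal brain and 12.57 ± 0.36 (SD, n = 4) in GL261 (exact permutation p = 0.486). With this level in the model the fold changes of called genes kept a median ratio of 1.00 to those without it (quartiles 0.938 and 1.06). A level so close in both groups could change them little, so the fit adds little to this. It shared 976 of the 1227 called genes. A difference in RNA 3' bias cannot be told apart from the tumour for the called genes, because the lowest normal brain Gapdh ratio, 2.39, exceeded the highest GL261 ratio, 1.89, by 0.50 and the groups do not overlap in it. The biological difference named by the labels, tumour against normal brain, remains an open explanation that was not separated from this ratio. The age of the mice, marrow transplantation and which macrophages the GFP sort took are open as well.

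Genes of other cell types differed in both directions. A lower share of macrophages that raised all other cell types alike is argued against by opposite directions among 9 cell type lists. On every GL261 array the B cell and endothelial means lay below those on every normal brain array. The oligodendrocyte precursor, pericyte and T and NK means lay above them. The erythroid, myelin, neuron and astrocyte means overlapped between the groups. A permutation over the 92 genes of these lists gave p = 1e-05 against 1 shared mean fold change, the smallest possible, but it treats co-varying genes as independent. Of the lists 3 were called up and 4 down, and none of these calls held with an estimated correlation. RNA of blood, B and endothelial cells in the normal brain preparations could account for part of the decreases, and 88.9% of the members of these lists (32 of 36) had lower values in GL261, with Hbb-b2 at log2 13.54 and Cldn5 at 9.77 in normal brain. RNA of non-myeloid tumour cells could account for oligodendrocyte precursor and pericyte genes, and 90.0% of them (18 of 20) had higher values in GL261, with Col1a1 at 10.02 and Sox10 at 8.73 there. Such RNA was not tested for the cell cycle and matrix genes, whose means were likewise highest in GL261 replicate 2 among the GL261 arrays. The source cells of the collagen, granzyme and T and NK increases were not determined either. RNA of blood, vessel or tumour cells cannot be told apart from expression by the macrophages, because each array measured the RNA of a whole preparation. The lists used here were picked for their direction and keep no call with an estimated correlation. Selection by F4/80 is expected to reduce such cells, though how far is not known, nor whether the normal brain mice carried GFP. For Gh and Ttr, among the largest decreases, the source of the RNA was not tested.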

How the results depend on the processing

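The control covariate and the joint removal of a pair of arrays were chosen after seeing the data, and the other settings before. Over all alternatives the count of called genes was 455 to 1485 and that of at least 2-fold changes 390 to 1051. With variances that do not follow the signal the counts were 455 and 419, and 425 of the 1227 called genes were shared; the cause was not tested. Without 1 array they were 542 to 1171 and 390 to 813, with fewer arrays in each fit. With the replicate block 1004 genes were called, 789 of them shared, and the replicate numbers did not pair the arrays (correlations of the deviations at equal numbers 0.0792, -0.00754 and 0.0310). Lists called numbered 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 20 to 24 without 1 array. Medians of 13 of the 42 lists took the other sign in some alternative, 11 of them lists that were not called in the values as deposited. Under quantile normalization these were, among others, the pan-macrophage list (0.11, called up), the lysosome list (0.19, called up), the MHC class II list (0.02, not called) and the ribosomal list (0.040, not called). The lysosome median took the other sign in 8 alternatives, and the list was called in 4 of them. The M2 list, whose test pointed down, was called up with all probe sets (0.50). The cause of these changes was not tested. Of 1685 comparisons of named genes with other settings 1514 kept direction and side of the threshold, 166 lost a call, 5 gained 1 and 0 reversed, and of 1001 fits without 1 array 802 kept both and 199 lost a call. For lists the numbers were 556 of 628 kept, 45 lost, 24 gained and 3 reversed, and 273 of 294 kept without 1 array. Signals under 4.19 to 4.70 on the log2 scale were not separated from background, and 48 called genes were at background in normal brain and 0 in GL261.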

Other observations

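The gene families here, and all their tests, were chosen after the values were seen, so the p-values describe the pattern and do not test it independently. Of 9 tested granzymes 7 rose and 0 fell in GL261 (median log2 fold change 4.01, or 2.66 with genes at background set to their lower bound). Gzmf, Gzmd and Gzme, cytotoxic granule proteases, were at least 9.93-fold, 6.88-fold and 6.33-fold higher, and Gzma rose by 1.03. The camera adjusted p over 16 families was 1.51e-06, with adjusted p = 0.113 with an estimated correlation, and 5 to 7 members were called without 1 array. All 6 guanylate-binding proteins, effectors of the interferon response, rose (median 1.80), among them Gbp2b by 4.02 and Gbp6 by 1.86. That family had a camera adjusted p of 1.51e-06 and adjusted p = 0.113 with an estimated correlation, and 5 members were called under median centring, 4 without normal brain replicate 3 or GL261 replicate 1 and 3 without GL261 replicate 3 or 4. Of 15 immunoglobulin genes and segments 8 fell and 0 rose (median -1.67), with a camera adjusted p of 3.78e-09 that held with adjusted p = 0.0171 with an estimated correlation. Igha, the heavy chain of IgA, fell by 1.91, and 5 members were called lower without normal brain replicate 3 or GL261 replicate 1.

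Of 25 collagen genes 10 rose and 0 fell (median 1.31, camera adjusted p = 1.51e-06, adjusted p = 0.113 with an estimated correlation), among them the cartilage collagen Col2a1 by 3.50, with 6 called without GL261 replicate 1, 2 or 4 and a median of 2.03 without GL261 replicate 3. Of 11 matrix metalloproteinases 7 rose and 0 fell (median 1.37, camera adjusted p = 5.33e-05, adjusted p = 0.0524 with an estimated correlation), including the stromelysins Mmp3 by 2.99 and Mmp10 by 2.78 and the membrane-bound Mmp14 by 1.37. Of 13 genes known from osteoclasts, the bone-resorbing cells, 6 rose and 0 fell (median 0.59, camera adjusted p = 4.97e-05, adjusted p = 0.113 with an estimated correlation). The osteoclast median was 1.02 without normal brain replicate 2. Ocstamp, which acts in osteoclast fusion, rose by 4.31, the phosphatase Acp5 by 2.89 and the chloride channel gene Clcn7 by 1.18. Without normal brain replicate 3, 1 metalloproteinase and 1 osteoclast gene were called lower. Of 16 vacuolar ATPase subunits 4 rose and 0 fell (median 0.40, camera adjusted p = 0.0224, adjusted p = 0.113 with an estimated correlation), with 2 called under median centring and without normal brain replicate 1, normal brain replicate 2 or GL261 replicate 3, and an adjusted p of 0.00484 to 0.111 without 1 array, the highest without normal brain replicate 1.

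Of 21 semaphorins and plexins 4 fell and 1 rose (camera adjusted p = 0.0483, and 0.0571 under median centring), and of 29 ABC transporters 3 fell and 1 rose (camera adjusted p = 0.0333), with adjusted p = 0.120 and 0.291 with an estimated correlation. The semaphorin call was lost without normal brain replicate 1 (0.130), normal brain replicate 2 (0.0683), GL261 replicate 3 (0.0582) or GL261 replicate 4 (0.0522), and the family's median was -0.24, or -0.39 without normal brain replicate 3. The ABC transporter call was lost without normal brain replicate 2 (0.0700), normal brain replicate 3 (0.0568) or GL261 replicate 4 (0.0802), and the family's median was -0.19, or -0.29 without normal brain replicate 3 and -0.08 without GL261 replicate 4. ABC transporters called lower numbered 1 in these 3 fits and without GL261 replicate 3, and 5 under median centring, and 0 were called higher without normal brain replicate 3 or GL261 replicate 1, 3 or 4. The remaining 7 of the 16 families were not called: organic anion transporters, claudins, small heat shock proteins, ADAM proteases, serpins, Sox factors and Ms4a proteins. The organic anion transporters (camera adjusted p = 0.0599) were called down without GL261 replicate 2 (0.0252) or GL261 replicate 3 (0.0398). Of the 143 named genes 51 had other probe sets, and in 5 (Mbp, Tap1, Tgfbr2, Pdk1 and Pfkl) another probe set had the other sign. In 12 called named genes a further probe set was not called and moved less than 0.5 times as far or the other way. The principal component that separates the groups carried 41.1% of the variance across arrays, and the next component, 20.8%, separated normal brain replicates 2 and 3. With normal brain replicate 1 and GL261 replicate 2 both left out, 860 genes were called, 535 higher and 325 lower.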
